A study of Mus musculus with 9 samples.

How the data were processed

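Single-cell 3' RNA sequencing of 9 libraries of mouse cells was analysed: 1 of MEFs, 1 of 3-day iTECs, 2 of untreated 12-day iTECs, 1 of 12-day iTECs with DMSO, 2 of 12-day iTECs with DAPT, 1 of 10-day iTECs with DAPT and 1 of 10-day iTECs in coculture with thymocytes. Per the labels' protocols, the cells came from MEFs with an inducible Foxn1 allele. Groups and replicate numbers were taken from the sample titles. No label states that replicates came from separate embryos or cultures, so p-values measure the spread between these samples, which may in part be technical. By Xist and Y-linked transcripts, however, the 2 DAPT libraries of day 12 differed in embryo origin. The spread that all comparisons share therefore takes in a difference of origin.

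The authors deposited, for each library, a matrix of raw UMI counts per gene and filtered barcode, with no normalization. Cell Ranger wrote the matrices (version 6.0.0 per the file headers), whereas the submitters' processing notes name Cell Ranger 7, Seurat 4 and the genome build mm10, and the annotation used for counting is not given in the sources used here. Each matrix listed 32285 mouse genes. A GFP or EGFP sequence was also listed in 6 of the matrices and had 0 UMIs in each, so it was left out. GFP was listed for the MEF, 3-day, DMSO and DAPT replicate 2 libraries and EGFP for both 10-day libraries. The untreated 12-day libraries and DAPT replicate 1 listed neither. Comparisons of untreated 12-day cells with MEFs, 3-day cells, DMSO or coculture therefore also cross this difference in processing. Counts of genes with near-identical copies or overlapping neighbours, such as members of the MHC and histone families, depend on how the counter split their reads and are uncertain. Gene coordinates are those of GENCODE vM21 on GRCm38 (mm10), counted from 1, and all genes given with coordinates are protein coding there.

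Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, 61355 of 66069. The filter removed the most from the DMSO library (1567 barcodes, of which 1394 exceeded the mitochondrial limit). The library totals of 206883499 to 433572351 UMIs limit precision little for the genes named: counting error is far below the spread between libraries for any gene over 1 CPM. Kept cells of all libraries were clustered together on log-normalised counts (2000 variable genes, 30 principal components, 20 exact nearest neighbours, Leiden resolution 0.5), which gave 15 clusters. Markers of cell types were fixed beforehand. Only 1 cluster was named from them, a macrophage-like one of 72 cells led by Apoe, Lyz2 and C1qb, and the others are referred to by number. These included cluster 3 (97.2% MEFs), clusters 4 and 7 (98.9% and 98.6% 3-day cells), cluster 6, led by Mt4, Ly6g6c and the hair keratin gene Krt33a, and clusters 5 and 12, whose cells had few UMIs (medians 1294 and 5740). Because no class of iTECs passed the marker check, sizes of clusters are not compared between groups and tests within a class were replaced by tests within clusters by number. Doublets were scored per library by simulation, and the top 0.8% per 1000 cells (3732 cells, 6.1%) were marked. They were kept in the results and removed as an alternative. Embryo origin was read from cells with at least 10000 UMIs by Xist and Y-linked transcripts, after the data had been seen. In the 10-day libraries 9.29% (DAPT) and 8.12% (coculture) of these cells held both kinds of transcript. Only 15.9% and 24.5% of those were marked as doublets, so removing the marked cells may leave doublets in.

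For gene tests, UMIs were summed per library over kept cells outside the macrophage-like cluster, since cells are not replicates. The quasi-likelihood test of edgeR 4.0.16 was run on these sums for 20135 genes left by its filter on low counts, with TMM scaling, in 1 fit of all 9 libraries and 7 groups. The 2 groups of 2 libraries gave 2 residual degrees of freedom (median prior 4.08, common biological coefficient of variation 0.38), and groups of 1 library were assumed to vary like them. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, over the genes of each of 6 comparisons. Log2 fold changes and SEs are from the fit. Folds are ratios of the UMIs summed over a group's libraries to their summed totals, with exact Poisson 95% intervals that cover counting error only. With 2 libraries the deeper one weighs more, so folds differ from the fitted values and from ratios of the mean CPM. A fold against a group with 0 UMIs was computed against 3 counts over the group and is a lower bound. DESeq2 1.42.0 was run on the same design as an alternative. Comparisons of 1 library with 1 library have no test and are given as log2 ratios of CPM with Poisson intervals. A gene list's median was then placed among 10000 random lists of the same size matched on expression, over members with at least 5 CPM in the higher library.

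Before the data were examined, the comparisons, the filters, the cell type markers, the alternatives marked as planned, 32 gene lists and the rule for named genes were fixed. The rule took Foxn1, the 6 largest rises and 6 largest falls among called genes with at least 20 CPM and no overlap between groups (leaving out predicted, mitochondrial and ribosomal protein genes), and up to 3 members of each list, or the member of smallest p where none was called. Genes shared by all 3 pairs of like origin were named after their values were seen. Lists were tested with camera of limma 3.58.1 (two-sided, preset correlation 0.01, adjusted over the lists of a comparison), and again with a correlation estimated from the data. Of 192 list tests 63 passed with the preset correlation and 0 with the estimated one. The tests were checked on simulated counts with 200 genes changed by known folds per comparison. Simulated libraries were drawn independently, with no difference of origin between them, so the shares recovered need not hold for the real libraries. In the comparison with MEFs 0% of 2-fold, 10.4% of 4-fold and 50.0% of 8-fold changes were recovered among 19599 simulated genes, and in that with 3-day cells 0%, 9.0% and 43.9% among 19611. For DMSO against untreated cells 6.0% of 4-fold changes were recovered and for the coculture 34.3%. Of the unchanged simulated genes between 2 and 20 were called per comparison. For the coculture these 20 stood beside 3, 23 and 44 recovered genes changed 2-fold, 4-fold and 8-fold. Against MEFs 8 stood beside 0, 7 and 33, and against 3-day cells 2 stood beside 0, 6 and 29. In each simulated comparison false calls were a larger part of all calls than the adjusted p-value threshold is meant to allow, least so against 3-day cells.

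To compare shares of cells with a UMI of a gene, each cell was thinned to 5000 UMIs and shallower cells were left out (80 to 958 per library). Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. For a count of 0 the limit given is 3 counts of the total, and it bears on cells with a UMI, not on cells that express the gene. The share among macrophage-like cells, all from the coculture and MEF libraries, is given as a guide to background from free RNA. It does not measure background in other libraries or for genes those cells express. Replicates were compared by a chi-square of their counts over genes, which per degree of freedom was 625.7 for the untreated and 1450.0 for the DAPT pair, far above sampling noise, so no library was taken for a copy of another.

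Alternatives planned were RLE size factors, DESeq2, no filter on low counts, fits of the compared libraries alone, leaving out each replicate, the replicate number as a block, every barcode or a stricter cell filter (2000 genes and 5%), removal of putative doublets, all kept cells, thinned totals, joined controls, another cluster resolution (1.0) and thinning to 2000 UMIs. Added after the data were seen were cell origin as a term, crossed pairing, clusters of few UMIs left out, joined controls with cell origin as a term, 1 fit of DAPT over 3 cell origins, and pairs of like origin with 1 untreated library. In the DAPT comparisons the origin term leaves DAPT replicate 2 against DMSO and DAPT replicate 1 against untreated cells. These are the same comparisons as those without the other DAPT replicate, not further checks. Crossed pairing set untreated replicate 1 with DAPT replicate 2, which no label does. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3.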

Results

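Single-cell 3' RNA sequencing was done on mouse embryonic fibroblasts (MEFs) and on cells derived from MEFs that carry an inducible Foxn1 allele. Foxn1 encodes the forkhead transcription factor that directs the differentiation of thymic epithelial cells (TECs), the stromal cells in which T cells develop, and the programmed cells are called induced TECs (iTECs) here. The 9 libraries fell into 7 groups: MEF control, iTECs at day 3, untreated iTECs at day 12 (2 libraries), iTECs at day 12 given DMSO, iTECs at day 12 given DAPT (2 libraries), iTECs at day 10 given DAPT, and iTECs at day 10 grown with thymocytes. DAPT inhibits gamma-secretase, the protease that releases the active part of Notch receptors, and DMSO is its solvent. DMSO and DAPT were given every 24 h for 7 days from day 5 to the 12-day cells, and DAPT for 5 days to the 10-day cells. The coculture lasted 5 days from day 5, with thymocytes of mouse embryos. The 9 count matrices held 66069 barcodes, 4680 to 9488 per library, and 206883499 to 433572351 UMIs (unique molecular identifiers) per library. After cells with under 500 genes or over 10% mitochondrial UMIs were left out, 61355 cells remained. The median per barcode lay between 23038 and 45273 UMIs and between 5081 and 6120 genes. Only the untreated and the DAPT groups of day 12 had replicates (n = 2 each), so all other values come from 1 library and their intervals cover counting error only.

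Libraries differed in the cells they were grown from. Xist, the RNA that silences an X chromosome in female cells, was seen without Y-linked transcripts in 94.4% to 98.7% of well-covered cells of the MEF, 3-day and both untreated 12-day libraries and in 95.2% of those of DAPT replicate 1. Y-linked transcripts without Xist were seen in 93.9% of the DMSO library's cells and 91.7% of those of DAPT replicate 2. Both 10-day libraries held a mixture, with Y-linked transcripts in 25.9% (DAPT) and 16.1% (coculture) of the cells that showed 1 of the 2 kinds. Across genes, log2 CPM (counts scaled to library size) of DAPT replicate 1 correlated with untreated replicate 2 at r = 0.996 and DAPT replicate 2 with DMSO at r = 0.996, against r = 0.977 between the DAPT replicates and r = 0.99 between the untreated ones. Genes are not independent replicates, and these r values only describe the libraries. DMSO and untreated cells therefore differed in embryo origin as well as in solvent, and their matrices in the reporter sequence listed (GFP against none). DAPT values are given below pooled and, for some genes and lists, within pairs of like origin.

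Foxn1 itself (ENSMUSG00000002057; chromosome 11, 78357577 to 78386558, minus strand, GRCm38) stood at 0.97 CPM in MEFs, 9.23 at day 3 and 16 ± 2.5 (SD, n = 2) in untreated cells at day 12. It stood at 8.30 CPM with DMSO, 8.26 ± 3.20 (SD, n = 2) with DAPT at day 12, 11.6 with DAPT at day 10 and 10.5 in coculture. These 3' counts do not tell transcripts of the inducible allele from those of the endogenous gene. The rise from MEFs to day 12 passed the test (log2 fold change 3.92, SE 0.606, adjusted p = 0.0123, 16.1-fold with a counting interval of 14.2 to 18.4). The day-12 value did not differ from day 3 by the test (log2 0.98, SE 0.508, adjusted p = 0.298). With each cell thinned to 5000 UMIs, Foxn1 was seen in 0.408% of MEFs (exact binomial interval 0.269 to 0.593), 4.73% of 3-day cells (4.30 to 5.18) and 7.99% (7.36 to 8.66) and 10.4% (9.40 to 11.5) of cells of the untreated 12-day libraries. It was seen in 4.34% with DMSO, 6.15% and 3.31% with DAPT at day 12, 5.81% with DAPT at day 10 and 5.92% in coculture. Without thinning the shares were 3.44%, 24.0%, 43.5%, 43.5%, 27.8%, 39.8%, 15.8%, 31.1% and 28.1% in the same order. Among 69 macrophage-like cells, which should lack Foxn1, 0 had a UMI after thinning, which allows up to 4.35% of cells with a UMI (3 counts of the total; median 11807 UMIs before thinning, against 26612 to 58281 in the other cells).

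**Figure D1:**
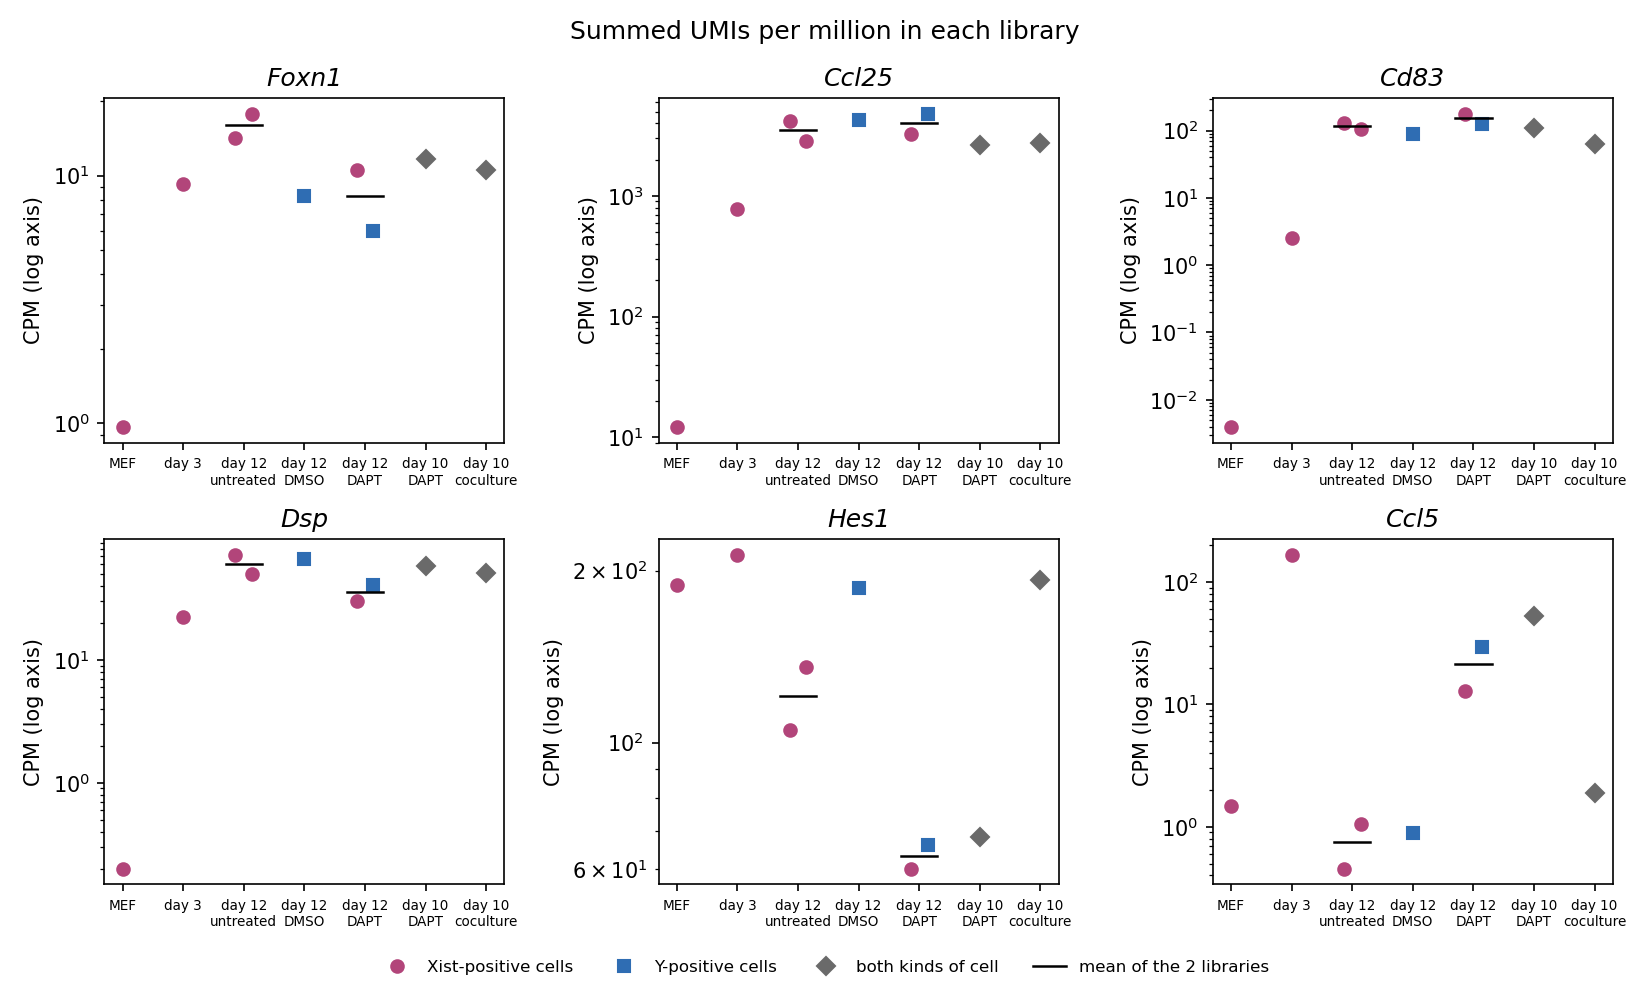
CPM from summed UMIs (log axis) of 6 genes in each of the 9 libraries, by group; symbols mark whether cells held Xist, Y-linked transcripts or a mixture, and bars are means of groups with 2 libraries. Hes1 lies between 60.2 and 68.5 CPM in the 3 DAPT libraries and between 105 and 213 CPM in the 6 others, while Ccl5 is above 10 CPM in the DAPT libraries and the 3-day library alone.

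The step from MEFs to day 3 was read from the 3-day library against MEFs, with no test because each group had 1 library. No uninduced library of day 3 or day 12 was among the samples, and no day is given for the MEFs. Induction of Foxn1 and time in culture therefore cannot be told apart in comparisons with MEFs. Interferon response genes, which are induced by viral or cytokine signals, stood far higher at day 3: all 19 measured members of that list were higher, with a median log2 ratio of 6.70, above all 10000 random lists of matched size and expression. Ifit1 (ENSMUSG00000034459; chromosome 19, 34640871 to 34650009, plus strand) differed by 11.28 on the log2 scale (95% counting interval 10.97 to 11.61), Ddx60 by 9.46 and the chemokine gene Ccl5 by 6.81. All 13 measured genes of MHC class I presentation were higher too (median 2.75, Psmb9 6.28, H2-K1 4.82). Foxn1 was 9.56-fold higher (log2 3.26, interval 3.07 to 3.45). Ccl25 (ENSMUSG00000023235; chromosome 8, 4325210 to 4360020, plus strand), a chemokine that attracts T-cell progenitors to the thymus, was 64.0-fold higher (6.0, 5.95 to 6.05). Of TEC function genes 9 of 11 were higher (median 1.82), as were 9 of 10 epithelial genes (1.86), among them Krt18 (7.06) and Dsp (6.80), with Ovol1 at least 453-fold higher. All 7 measured pharyngeal pouch transcription factors were higher (median 1.18, Hoxa3 1.82, Meis1 1.33), and 7 of 8 Notch targets were (1.42, Dtx1 8.67, Dtx3l 3.52), as were 14 of 20 genes of Wnt and FGF signalling (0.86, Nkd1 5.03, Axin2 4.19, Tcf7 3.82). The Notch target Hes1 differed far less, at 212.9 CPM at day 3 and 188.9 in MEFs, and activity of the pathway was not tested. Lower at day 3 were all 22 cell cycle genes (median -1.23, Rrm2 -1.47, Ccnb1 -1.40), all 16 genes of cholesterol synthesis (-0.76, Insig1 -1.33) and 12 of 14 contractile genes (-0.47, Des -3.77, Tagln -1.07). The lowest ratios included Igfbp5 (-4.60), Mcpt8 (-3.73) and Crabp1 (-3.58), and Vim stood at -2.07 and Thy1 at -1.76. Scaling by TMM would move every 3-day ratio by -0.31, which turns the direction of none of the list medians given here.

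**Figure D2:**
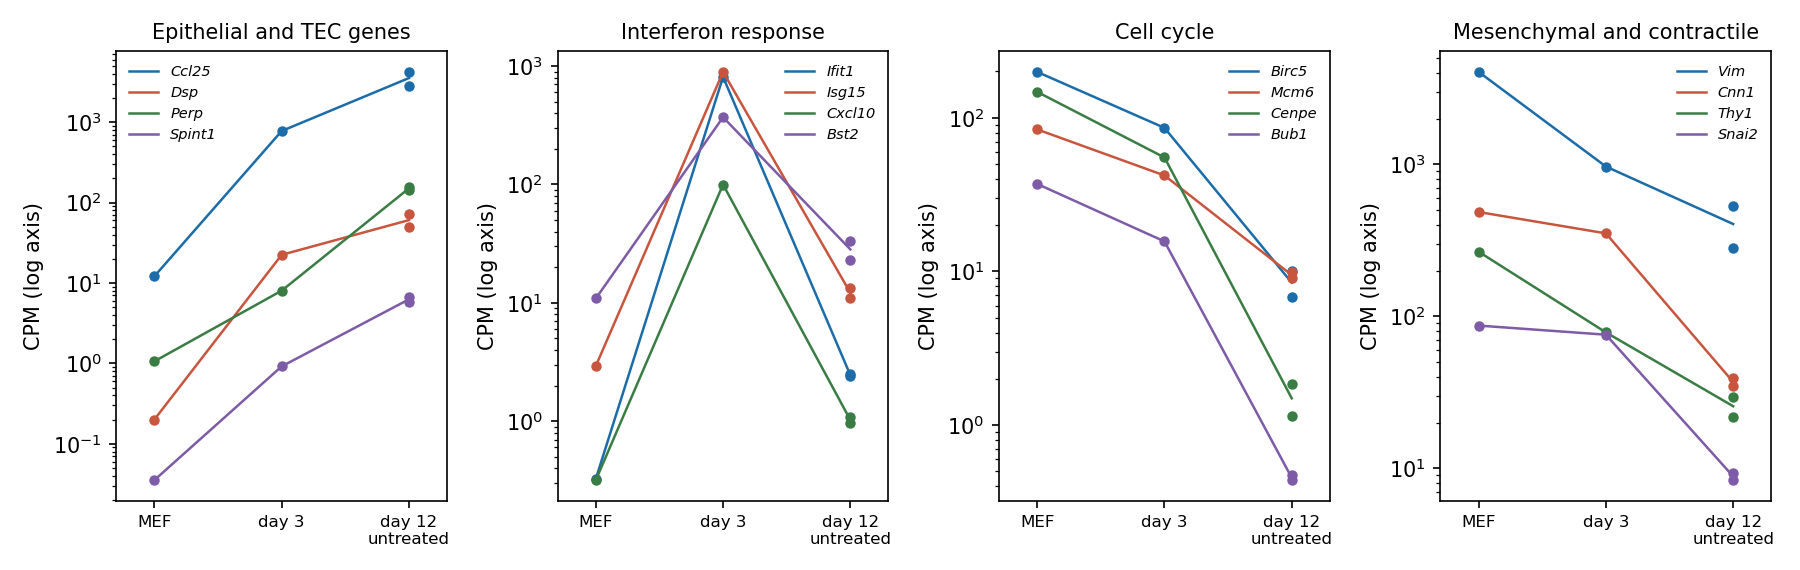
CPM (log axis) of 16 genes in MEFs, 3-day cells and untreated 12-day cells; points are libraries and lines join the MEF and 3-day values to the mean of the 2 libraries of day 12. Isg15 reaches 893 CPM at day 3 and 12.2 ± 1.62 (SD, n = 2) at day 12, whereas Vim goes from 4062 CPM in MEFs to 405 ± 175 at day 12.

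After 12 days the untreated cells had gained epithelial and TEC transcripts and lost those of dividing and contractile cells. Against MEFs, 2160 genes rose and 1972 fell (edgeR quasi-likelihood test, adjusted p under 0.05, 20135 genes tested). Folds are of UMIs pooled over the libraries of a group, so the deeper library weighs more and they differ from ratios of the group means. Ccl25 rose 307-fold (296 to 318), to 3534 ± 962 CPM (SD, n = 2) from 12.1 CPM (log2 8.07, SE 0.646, adjusted p = 0.00466). Cd83, a surface protein of TECs needed for CD4 T-cell selection, rose to 118 ± 17.0 CPM from 1 UMI in MEFs (ratio 30800, interval 5520 to 1220000, adjusted p = 0.00299). The Notch ligand gene Dll4, a target of Foxn1 that commits progenitors to the T lineage, rose to 21.4 ± 7.97 CPM, also from 1 UMI (5060-fold, 907 to 200000, adjusted p = 0.0037). In the list of TEC function genes 9 members rose and 2 fell of 18 tested (10 and 2 adjusted over the list alone), and the stromal chemokine gene Cxcl12 was among those that fell (19.8-fold). Of 32 epithelial genes 21 rose and 1 fell (26 and 1 adjusted over the list alone), including Dsp (desmoplakin, 317-fold), Spint1 (180-fold) and Ovol1 (at least 1400-fold). Among keratinocyte genes 5 of 18 rose, such as Trp63 (146-fold, 49.8 to 710) and Perp (143-fold, 150 ± 8.0 CPM). The largest rises with 0 UMIs in MEFs were Pmch (137 ± 164 CPM and so very unequal between the 2 libraries, at least 14300-fold by pooled UMIs), Npy6r (at least 7590-fold) and Slc22a7 (at least 5800-fold). By limma's competitive set test, camera, the epithelial list (median log2 5.82, or 5.05 with genes at 0 set to their bound, adjusted p = 3.1e-13), the TEC list (2.35, adjusted p = 5.28e-05) and the keratinocyte list (3.76, bound 3.28, adjusted p = 0.000798) moved up against other genes. With an estimated correlation in place of the preset one, the adjusted p of each was 0.566.

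Genes of proliferation fell together in the same comparison: all 22 cell cycle genes fell over all genes tested and adjusted over the list alone, with Birc5 24.7-fold lower and Mcm6 8.76-fold lower, and the mitotic motor gene Cenpe fell 105-fold (97.9 to 113). Contractile genes fell in 12 of 15 cases (13 adjusted over the list alone), such as Cnn1 (13.4-fold, 37.0 ± 3.14 against 486 CPM). Of fibroblast and matrix genes 9 of 25 fell and 1 rose (10 and 2 adjusted over the list alone), with Fbln2 18.2-fold and Vim 10.9-fold lower, and 7 of 13 regulators of epithelial-mesenchymal transition fell (7 adjusted over the list alone, where 2 rose), such as Snai2 (9.97-fold), Foxc2 (8.96-fold) and Snai1 (6.10-fold). In cholesterol synthesis 8 of 16 genes fell (9 adjusted over the list alone), such as Msmo1 (2.48-fold) and Cyp51 (2.59-fold). The set test gave adjusted p = 6.88e-24 for the cell cycle (median -5.52), 1.75e-13 for contractile genes (-2.49), 3.17e-05 for fibroblast genes (-1.48), 0.00525 for transition regulators (-1.83) and 0.000798 for cholesterol synthesis (-1.22). Each of these had adjusted p = 0.566 with an estimated correlation. Single genes of other groups also changed: Cdkn1a, which halts the cell cycle, rose 5.38-fold (2351 ± 184 against 430 CPM), Igfbp3 93.9-fold, Bnip3 23-fold and H2-K1 9.42-fold, whereas Fgf7 fell 29.7-fold, Vegfa 7.35-fold, Hk2 5.99-fold and Jag1 5.38-fold. The Notch genes Dtx1 (633-fold, 395 to 1090) and Jag2 (528-fold) rose, but the list of Notch targets did not move as a set (1 of 15 rose, 1 fell, adjusted p = 0.852). Without untreated replicate 1 the test called 1121 genes and without replicate 2 it called 1506, while leaving out DAPT replicate 1 or 2, which only enter through the shared spread, gave 7826 and 7849. Of the 92 named genes called, 31 lost the call without untreated replicate 1 and 26 without replicate 2 (1120 and 1453 of the genes called then were also called with all libraries, 0 of them in the opposite direction).

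Between day 3 and day 12 interferon genes fell, and most epithelial genes had positive log2 fold changes, few of which passed over all genes. In untreated 12-day cells 96 genes rose and 118 fell against the 3-day library. Interferon response genes fell in 10 of 20 cases (19 adjusted over the list alone): Ifit1 328-fold (311 to 346; log2 -8.18, adjusted p = 0.0422), Ccl5 247-fold, Cxcl10 98.8-fold and Isg15 75.3-fold. MHC class I genes fell in 2 of 14 cases (10 adjusted over the list alone), with Psmb8 50.2-fold and H2-Q7 66.1-fold lower. The rises included Ly6g6c (4650-fold, 2140 to 12700), Lamb3 (89.5-fold), Cd83 (48.2-fold), Perp (18.9-fold) and Pkp3 (15.6-fold). Of 32 epithelial genes 31 had a positive log2 fold change, of which 2 passed over all genes, while adjusted over the list alone 15 rose and 1 fell. Of 22 cell cycle genes 2 fell (21 adjusted over the list alone; Birc5 10.7-fold), and of 15 contractile genes 2 fell (11 adjusted over the list alone; Cnn1 9.66-fold, Myh11 11.7-fold). Snai2 (8.68-fold) and the chondrocyte genes Sox9 (11-fold) and Col2a1 (12.2-fold) fell as well. The set test gave adjusted p = 3.58e-29 for interferon genes (median -4.08), 5.13e-23 for the cell cycle (-3.87), 6.49e-10 for epithelial genes (2.49), 1.94e-09 for contractile genes (-1.37) and 5.97e-09 for MHC class I (-1.43). With an estimated correlation each of these 5 had adjusted p = 0.542. The number of calls rested on single libraries: it was 6 without untreated replicate 1, 50 without untreated replicate 2, 3929 without DAPT replicate 1 and 3949 without DAPT replicate 2. This comparison shares the untreated libraries with that against MEFs, so part of any likeness between them comes from those libraries.

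The DAPT libraries address what Notch signalling does in iTECs after day 5. At day 12, Hes1 (ENSMUSG00000022528; chromosome 16, 30064384 to 30067796, plus strand), the classical Notch target, stood at 60.2 and 66.3 CPM with DAPT, 186 with DMSO, and 105 and 136 in untreated cells. Against DMSO its log2 fold change was -1.37 (SE 0.283, unadjusted p = 0.00277, adjusted p = 1.0). Heyl (ENSMUSG00000032744; chromosome 4, 123233556 to 123249875, plus strand) was 41.4-fold lower by pooled UMIs (22.2 to 87.1) than in untreated cells, at 0.01 and 0.03 CPM against 0.87 and 0.11 (log2 -5.03, unadjusted p = 0.00618, adjusted p = 1.0). Ccl5 (ENSMUSG00000035042; chromosome 11, 83525778 to 83530518, minus strand) stood at 13 and 29.7 CPM with DAPT against 0.891 with DMSO and 0.456 and 1.05 untreated (log2 4.74 and 4.77 against DMSO and untreated). Cxcl10 (ENSMUSG00000034855; chromosome 5, 92346638 to 92348889, minus strand), also induced by interferon, had log2 fold changes of 4.28 and 4.38. Dll4 was 2.39-fold higher than in untreated cells (log2 1.15, unadjusted p = 0.0101, adjusted p = 1.0). Foxn1 had a log2 fold change of 0.21 (SE 0.491) against DMSO and -0.96 (SE 0.401, unadjusted p = 0.0526) against untreated cells. No gene passed the adjusted test against DMSO (edgeR 0, with 326 at unadjusted p under 0.05; DESeq2 called 7 higher and 8 lower) or against untreated cells (edgeR 0, with 488 at unadjusted p under 0.05; DESeq2 13 higher and 28 lower). The 326 and 488 are smaller shares of the 20135 genes tested than the 5% and 4.99% of unchanged simulated genes under that p. They show no excess of small p-values. With cell origin as a term edgeR called 11 genes against DMSO and 4 against untreated cells, with crossed pairing 116 and 4, and in the fit over 3 cell origins 1, Ccl5 (adjusted p = 0.0232). The origin term leaves DAPT replicate 2 against DMSO and DAPT replicate 1 against untreated cells. Crossed pairing, which sets untreated replicate 1 with DAPT replicate 2, was fitted after the data were seen. It rests on no label and takes up part of the residual spread, so its calls are no evidence of a DAPT effect. In simulated data, which held no difference of origin, this test recovered 13.4% of genes changed 4-fold and 43.9% of those changed 8-fold against DMSO, and 35.8% and 68.2% against untreated cells. Leaving out DAPT replicate 2 sets DAPT cells with Xist against DMSO cells with Y-linked transcripts. Leaving out DAPT replicate 1 sets DAPT cells with Y-linked transcripts against untreated cells with Xist. Origin and DAPT differ together in these 2 comparisons, which gave far more calls than those of like origin.

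As sets, Notch targets had lower values with DAPT than with DMSO in 12 of 15 members (median log2 -0.48; 0 members passed over all genes and 2 adjusted over the list alone; camera adjusted p = 2.81e-05, and 0.574 with an estimated correlation). Against untreated cells 8 of 15 were negative (adjusted p = 0.14). Fibroblast and matrix genes were negative in 20 of 25 cases against DMSO (median -0.80, adjusted p = 1.57e-06, and 0.583 with an estimated correlation), and in 15 of 25 against untreated cells (-0.30, 0.00409 and 0.57). The call against untreated cells ended without untreated replicate 1 (median 0.0986, adjusted p = 0.394) and without DAPT replicate 1 (-0.00441, adjusted p = 0.866). Keratinocyte genes were negative in 16 of 18 cases against DMSO (median -1.39, adjusted p = 1.03e-12, 0.574 with an estimated correlation), and Krtdap, a gene of differentiating keratinocytes, stood at 4.73 CPM with DMSO and under 0.1 CPM in the untreated and DAPT libraries of day 12. MHC class I genes were positive in 14 of 14 cases against untreated cells (0.52, adjusted p = 5.21e-06, 0.57 with an estimated correlation), and interferon genes in 19 of 20 (0.71, 2.33e-07 and 0.57). The interferon call ended without DAPT replicate 2 and, which is the same comparison, with cell origin as a term. Against DMSO neither list was called (MHC class I 8 of 14 positive, 0.06, adjusted p = 0.875; interferon 11 of 20, 0.08, 0.473). Cell cycle genes went opposite ways by control: all 22 were negative against DMSO (median -1.01, adjusted p = 2.01e-11, 0.662 with an estimated correlation) and all 22 positive against untreated cells (1.17, 4.86e-11 and 0.57). The call against untreated cells ended without DAPT replicate 2 and, again the same comparison, with cell origin as a term. With joined controls and cell origin as a term the call against DMSO ended too (median -0.0895, adjusted p = 0.092). Immediate early and heat shock genes, which respond to cell handling, were positive in 14 of 16 cases against untreated cells (0.36, adjusted p = 0.000551, 0.57 with an estimated correlation). Their call ended without untreated replicate 2, and without DAPT replicate 2 or, the same comparison, with cell origin as a term. Against DMSO they were not called (6 of 16 positive, -0.15, adjusted p = 0.28).

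Within pairs of like origin, DAPT replicate 1 was set against the untreated mean, DAPT replicate 2 against DMSO, and 10-day DAPT against the coculture, so that no library was used more than once. In the last pair DAPT and coculture differ together. Of 9287 genes measured in all 3 pairs, 3 were over 2-fold higher with DAPT in each (Ccl5, log2 4.10, 5.06 and 4.82; Cxcl10, 2.69, 4.93 and 4.85; Ifit1, 1.64, 2.93 and 3.23) and 15 over 2-fold lower. The 15 included Hes1 (-1.0, -1.49 and -1.49), the neuropeptide gene Nts (-2.20, -3.63 and -3.02), the growth factor genes Pgf (-2.25, -1.51 and -1.85) and Fgf2 (-1.04, -1.25 and -1.30), and the matrix genes Aspn (-2.56, -2.15 and -1.50), Ogn (-1.95, -1.11 and -1.22) and Col15a1 (-2.85, -1.37 and -1.12). With each pair's ratios shuffled over the genes, 0.0 genes were shared in each direction on average. Shuffling treats all genes as equally variable and removes the correlation between pairs, so it does not exclude chance. Against untreated replicate 1 alone in the first pair, 16 of the 18 genes stayed over 2-fold, not Hes1 (-0.81) or Fgf2 (-0.93). Against untreated replicate 2 alone 12 stayed, with smaller values for Aspn (-1.88), Pgf (-1.30) and Ogn (-1.315), while Cryba4 turned (0.17), Gper1 (-0.08) and Arhgap42 (-0.68) came under 2-fold, and Col15a1 (-1.42), Adamts12 and Tafa4 stood under 5 CPM in that pair. Across all 9287 genes the pairs' log2 ratios correlated at r = 0.376, 0.354 and 0.308, and 56.6%, 55.3% and 43.5% of genes had the same sign in the same 3 combinations (replicate 1 pair with replicate 2 pair, replicate 1 pair with 10-day pair, and replicate 2 pair with 10-day pair). With untreated replicate 1 alone in the first pair, the first 2 of these r values were 0.214 and 0.277. With untreated replicate 2 alone they were 0.528 and 0.376. Fibroblast genes had median ratios of -0.91, -0.65 and -0.50, and Notch targets of -0.24, -0.25 and -0.12. All pair ratios are of CPM without TMM scaling and are given without matched random lists, so small medians do not fix a direction. MHC class I genes had medians of 0.20 (5 of 9 higher), 0.075 (8 of 12) and -0.05 (4 of 10), keratinocyte genes of 0.06 (3 of 5 higher), -0.42 (2 of 7) and -0.69 (1 of 6), and immediate early and heat shock genes of -0.003, -0.009 and 0.175. Cell cycle genes had medians of 0.08, -0.48 and 0.36 and contractile genes -0.48, 0.08 and -0.47, so neither list moved alike in all 3 pairs. Cd83 was higher in each pair (0.60, 0.49 and 0.83), whereas Foxn1 was not (-0.61, -0.47 and 0.15).

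**Figure D3:**
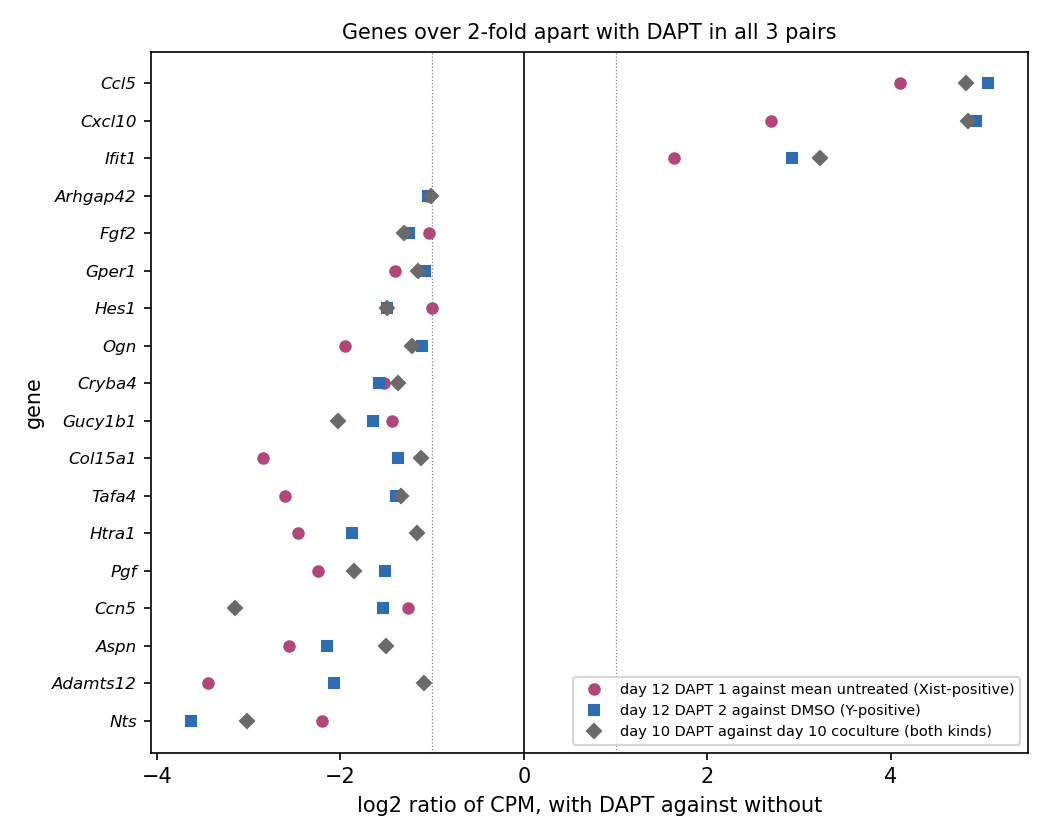
Log2 ratio of CPM with DAPT against without, for the 18 genes over 2-fold apart in the same direction in all 3 pairs of libraries of like origin; each point is 1 pair and dotted lines mark a 2-fold difference. Ccl5, Cxcl10 and Ifit1 lie on the higher side, and 15 genes, from Nts to Arhgap42, on the lower side.

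DMSO alone, the solvent, was compared with untreated cells at day 12, with embryo origin differing between the groups. All 22 cell cycle genes had positive log2 fold changes (median 2.20; 17 passed adjusted over the list alone and 0 over all genes; camera adjusted p = 1.06e-23, and 0.661 with an estimated correlation), with Aurkb at 3.18. Keratinocyte genes were positive in 15 of 18 cases (1.24, 4.23e-08 and 0.661), Krtdap at 7.09 (unadjusted p = 0.000184). Interferon genes were positive in 14 of 20 cases (0.77, adjusted p = 0.00957, and 0.767 with an estimated correlation), and MHC class II genes negative in all 8 (-0.88, 0.03 and 0.661). MHC class I genes were positive in 12 of 14 cases (0.43, 0.00957 and 0.661), as were immediate early and heat shock genes in 11 of 16 (0.59, 0.00161 and 0.661). The immediate early gene Zfp36 stood at 2.48, the receptor gene Pdgfra at 2.24, the Notch ligand gene Jag1 at 1.10 and Foxn1 at -1.17 (SE 0.514, unadjusted p = 0.062, adjusted p = 0.712). edgeR called 0 genes, with 898 at unadjusted p under 0.05, and DESeq2 called 9 higher and 5 lower. The 898, and the 192 given below, are smaller shares of the genes tested than the 4.8% of unchanged simulated genes under that p. Leaving out DAPT replicate 1 or 2, which enter only through the shared spread, gave 576 and 574 calls. With cell origin as a term, which the DAPT libraries let the fit estimate if origin acts alike with DAPT, 0 genes were called and 192 had unadjusted p under 0.05, and Bcl11b went from 2.40 to -0.316 and Twist1 from 0.98 to -0.257.

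Coculture with fetal thymocytes was set first against untreated 12-day cells, after macrophage-like cells were left out. The day differed as well, and so did cell origin (a mixture against cells with Xist), for which no term was fitted here. C1qb (ENSMUSG00000036905; chromosome 4, 136880129 to 136886187, minus strand), a complement gene of macrophages, had 1 UMI in the untreated libraries and a log2 fold change of 9.61 (1080-fold, 193 to 42700; unadjusted p = 0.000141, adjusted p = 0.664). The MHC class II gene H2-Aa was 17.6-fold higher (12.9 to 24.5), Pdgfra 8.32-fold and Notch1 4.89-fold. Macrophage genes were positive in 10 of 11 cases (median 5.97, or 4.77 with genes at 0 set to their bound; 9 passed adjusted over the list alone; camera adjusted p = 1.23e-22, and 0.414 with an estimated correlation). Fibroblast genes were positive in 19 of 25 cases (0.73, 2e-05 and 0.858), cell cycle genes in 21 of 22 (1.15, 8.76e-07 and 0.858), MHC class II genes in 6 of 8 (1.08, 0.0165 and 0.858) and Notch targets in 13 of 15 (0.50, 0.0468 and 0.858). The Notch target call ended without untreated replicate 2 or without either DAPT replicate. Foxn1 stood at -0.78 (SE 0.504) and Cd83 at -1.09. No gene passed over all genes (edgeR 0, with 1393 at unadjusted p under 0.05; DESeq2 82 higher and 75 lower), and leaving out either DAPT replicate gave 675 calls.

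Against the only other 10-day library, that given DAPT, coculture and inhibitor differ together and no test applies. Hes1 was higher in coculture by 1.49 on the log2 scale (1.47 to 1.52), Notch1 by 1.27 and Hey1 by 0.95, and 6 of 8 measured Notch targets were higher (median 0.12, percentile 97.6 of the random lists). All 23 fibroblast genes were higher (median 0.50), with Lox at 1.31, Pdgfrb at 1.21 and Fbln2 at 1.10, as were 12 of 13 contractile genes (0.47) and 5 of 6 keratinocyte genes (0.69, Krt16 3.00, of which Krt16 and Sprr1a turned with cell origin). The matrix genes Ccn5 (3.15) and Eln (2.31) and Nts (3.02) had some of the highest ratios. Lower in coculture were Cxcl10 (-4.85), Ccl5 (-4.82, -4.96 to -4.69) and Ifit1 (-3.23), 9 of 10 interferon genes (median -0.40), all 18 cell cycle genes (-0.36), all 15 genes of cholesterol synthesis (-0.33), and the TEC genes Cd83 (-0.83), Kitl (-0.66) and Dll4 (-0.60). Foxn1 stood at -0.15 (-0.23 to -0.07). The ratios were also taken apart into cells with Xist and cells with Y-linked transcripts. This was done for 337 genes, which were named genes and list members and not a sample of all genes. Of 254 whose 2 counting intervals both left out 0, 237 had the same direction in both kinds of cell and 17 the opposite one. Values were alike for Hes1 (1.41 and 1.63), Cd83 (-0.88 and -0.88), Pdgfrb (1.14 and 1.34) and Foxn1 (-0.11 and -0.18), but turned for Krt16 (4.24 and -0.98), Sprr1a (2.19 and -3.96), Gal (3.70 and -2.16), Rab25 (0.89 and -2.36) and Ccl25 (0.08 and -0.36).

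The coculture held few blood cells in the kept data. A cluster led by Apoe, Lyz2 and C1qb, macrophage-like by its markers, made up 0.806% of coculture cells (57 of 7073; exact 95% interval 0.611 to 1.043) and 0.221% of MEFs (15 of 6794; 0.124 to 0.364), and had 0 cells in the 7 other libraries, where 3 counts of the total, the limit given for a count of 0, made up 0.033% to 0.070%. A single coculture cell of 7073 held UMIs of at least 2 Cd3 genes and at least 5 T-lineage markers. In the other libraries 0 cells did, and the coculture's own limit for a count of 0 would be 0.0424%.

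With DAPT, day 10 was set against the mean of day 12, again with no test and with a mixture of origins at day 10. Of fibroblast genes 19 of 22 were higher at day 10 (median log2 ratio 0.69; Fbn1 1.56, Postn 1.49, Col3a1 1.44), and so were 12 of 13 contractile genes (0.43, Lmod1 1.33) and 17 of 18 cell cycle genes (0.57, Mki67 1.43, Top2a 1.26). Matched random lists had medians of 0.016, 0.016 and 0.223 for these 3 lists. Scaling by TMM (factors 1.115 at day 10, 0.909 and 1.027 at day 12) would lower all ratios of this comparison. Lower at day 10 were 11 of 16 epithelial genes (-0.26, Spint2 -1.23, Krt19 -1.18), all 5 measured keratinocyte genes (-0.73, Sprr1a -2.12) and 9 of 12 chemokine and cytokine genes (-0.43, Ccl25 -0.60). Gal (3.54) and Mylk (2.18) were among the highest ratios and Nppb (-3.84) and Spp1 (-3.35) among the lowest, and Foxn1 stood at 0.49.

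Thinned to 5000 UMIs per cell, other TEC genes were seen in more iTECs than MEFs. Ccl25 was seen in 5.75% of MEFs (5.20 to 6.34), 47.2% of 3-day cells (46.1 to 48.2) and 52.0% to 74.2% of cells in the 10- and 12-day libraries, against 24.6% of macrophage-like cells. Dll4 was seen in 0 of 6613 MEFs, which allows up to 0.045%, in 2.06% of 3-day cells (1.78 to 2.37), 7.84% and 11.8% of untreated 12-day cells and 19.1% and 21.6% of 12-day cells with DAPT, 15.6% with DMSO, 14.4% with DAPT at day 10 and 9.36% in coculture, against 1.45% of macrophage-like cells. Krt8 varied with the library, at 34.3% and 17.3% in untreated, 49.4% in DMSO and 24.9% and 72.7% in DAPT cells of day 12, and so did Psmb11, the catalytic subunit of the thymoproteasome (4.18%, 1.63%, 12.8%, 1.75% and 16.8%). Macrophage-like cells showed Krt8 in 11.6% (5.14 to 21.6), an interval that includes the 17.3%, and Psmb11 in 1.45% (0.037 to 7.81), which includes the 4.18%, 1.63% and 1.75%. Hes1 was seen in 17.9% to 22.0% of cells of the 3 DAPT libraries and in 32.6% to 52.5% of cells of the other libraries. Macrophage-like cells showed Hes1 in 20.3% (11.6 to 31.7), but they may express it themselves. These cells came from the coculture and MEF libraries alone, so their shares do not measure background in the others. Epcam was seen in 0.045% of MEFs, 0.143% of 3-day cells and 0.606% to 2.36% of cells of the 10- and 12-day libraries. It was seen in 4 of 69 macrophage-like cells (5.80%, interval 1.60 to 14.2). By cluster Epcam stood at 6.20 CPM in cluster 0 and 8.28 in cluster 6, against 0.243 in cluster 8 and 0.07655 in cluster 3, which held MEFs. The macrophage-like cluster of 72 cells had the highest value, 11.3 CPM, on few UMIs. Those cells therefore give no lower background for Epcam, and whether the iTEC shares exceed free RNA was not decided.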

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

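The tests in this part were chosen before the values they measure were seen. The macrophage-like cluster stood out because its share in the coculture library, 0.806% (57 of 7073 cells), lay above its share in the MEF control, 0.221% (15 of 6794 cells), in cells that the comparisons leave out. Each share comes from 1 library, so counting intervals (0.611 to 1.043 and 0.124 to 0.364) say nothing of the spread between cultures. With putative doublets removed the shares were 0.856% and 0.234%, and at the higher cluster resolution the same 72 cells formed the cluster.

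Macrophage and MHC class II transcripts were also found in coculture cells outside that cluster: C1qb at 1.91 CPM (4273 CPM inside), Lyz2 at 3.12 (5154), H2-Aa at 1.44 (2799) and Cd74 at 28.2 (8543), against 0.0014, 0.855, 0.0879 and 19.2 CPM on average in untreated 12-day cells. Undetected doublets of macrophage-like cells are a candidate source, since 61.0% of the 3560 macrophage-list UMIs outside the cluster lay in 30 cells with at least 5 of them, where the majority had been predicted. Whether free RNA or doublets of these cells account for the class II genes too stays open: the ratio of class II to macrophage UMIs was 2.07 times that inside the cluster (median over pairs of 8 and 11 genes, interval 1.03 to 7.05), which includes values on both sides of the predicted bounds. A higher level of class II genes in the iTECs of the coculture, the biological alternative, cannot be told apart from it with these counts.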

How the results depend on the processing

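Cell origin as a term, crossed pairing, joined controls with cell origin, the fit over 3 cell origins, pairs of like origin and tests within clusters were chosen after results were seen. For named genes, 1938 values under alternatives of 125 calls kept direction and side of the threshold, and 187 lost the call. For named genes with no test, 398 values counted as the same (16 with a change of sign) and 270 as moved (13 with one). Of shares of cells with a UMI, 16 values stayed within the main interval and 198 moved when the thinning was changed. Of the values of the 63 list calls 326 stayed, 109 lost the call and 3 reversed, and with an estimated correlation 0 of 63 list calls remained. The number of genes called depended on which libraries set the spread and on the terms of the fit, and where no cause is named the cause was not tested. Against MEFs (4132 calls), fitting the compared libraries alone gave 7849, cell origin as a term 7822, and leaving out 1 replicate 1121 to 7849. Against 3-day cells (214), DESeq2 gave 2655, no low-count filter 2513, the compared libraries alone 4009, the stricter cell filter 324, cell origin 3894, and leaving out 1 replicate 6 to 3949. DESeq2 called all 214 genes again and 3996 of the 4132. RLE size factors split the 3-day calls into 83 up and 85 down.

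For DAPT, besides the 2 planned comparisons, fits were run with joined controls, with cell origin, with both, within 5 clusters and over 3 cell origins. In the planned comparisons the fit with cell origin equals that without DAPT replicate 1 (against DMSO) or without DAPT replicate 2 (against untreated cells). Leaving out the other DAPT replicate instead sets cells of unlike origin against each other, and those fits gave the most calls. Against DMSO (0), DESeq2 gave 15, no filter 17, cell origin 11, and leaving out 1 replicate 0 to 690. Against untreated cells (0), DESeq2 gave 41, no filter 50, cell origin 4, and leaving out 1 replicate 0 to 684. Joined controls with cell origin gave 0 (1151 at unadjusted p under 0.05; leaving out 1 replicate 4 to 363). The fit over 3 cell origins gave 1 call, Ccl5 (adjusted p = 0.0232; Hes1 0.108), 0 without the 10-day libraries and 0 to 410 with 1 replicate left out. The 410 arose without untreated replicate 1 alone, and its mixed pair confounds DAPT with coculture. Within clusters, leaving out 1 replicate gave 0 to 54 calls in cluster 0 (0 with all), 0 to 516 in cluster 1 (0), 14 to 515 in cluster 5 (0) and 1 to 167 in cluster 8 (1). For DMSO against untreated cells (0), DESeq2 gave 14, no filter 89, and leaving out 1 replicate 0 to 576. For coculture against untreated cells (0), DESeq2 gave 157, no filter 220, the compared libraries alone 463, and leaving out 1 replicate 0 to 675.

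With the replicate number as a block, the fits called 1492 genes against MEFs, 5 against 3-day cells, 2 for DMSO and 2 for coculture against untreated cells, 49 in cluster 5 and 4 in cluster 8. The numbers do not pair the samples: deviations of same-numbered libraries correlated at r = -0.522. Crossed pairing (untreated replicate 1 with DAPT replicate 2) gave 7452, 4000, 1154 and 1405 calls in the same comparisons, 116 for DAPT against DMSO and 4 against untreated cells. No label pairs these libraries, and with deviations of opposite sign the crossed term takes up residual spread. More calls under it are therefore no evidence of an effect.

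The 18 genes over 2-fold apart in all 3 pairs of like origin were 21 against untreated replicate 1 alone and 12 against replicate 2 alone. Genes whose value changed sign had not been called, whereas 2 lists had. For DAPT against DMSO, Foxn1 (0.21) was -0.37 with cell origin, -0.67 with joined controls and -0.37 to 0.62 with 1 replicate left out (-0.37 without DAPT replicate 1). For DAPT against untreated cells, Cd74 (-0.87) was 0.0529 without untreated replicate 1 (leaving out 1 replicate -1.43 to 0.0529), and Kdr (0.285) was -0.36 with cell origin, -0.36 without DAPT replicate 2 and -0.0722 without untreated replicate 2 (-0.36 to 0.761 over the replicates left out). With cell origin, DMSO against untreated cells gave Twist1 -0.257 (0.98), Chac1 0.133 (-0.98) and Bcl11b -0.316 (2.40). Without untreated replicate 1 the fibroblast list went from -0.30 to 0.0986 (-0.863 to 0.0986 over the replicates left out, with -0.00441 without DAPT replicate 1), and the contractile list from -0.346 to 0.0863 (-0.486 to 0.0863). Foxn1 at day 3 against MEFs had a ratio of 2.95 after TMM scaling (3.26 without). Depth set the share of cells with a Foxn1 UMI: in untreated replicate 1 it was 3.51% at 2000 UMIs, 7.99% at 5000 and 43.5% without thinning.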

Other observations

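The tests of embryo origin, the pairs of like origin and the test of the rise that macrophage genes would need were chosen only after the results they bear on were seen.

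Some gene groups not described above also moved. Under DAPT, neural genes had negative log2 fold changes against untreated 12-day cells in 6 of 8 cases (median -0.85; 0 passed over all genes and 3 adjusted over the list alone; camera adjusted p = 6.34e-05, and 0.57 with an estimated correlation). Stmn2, a microtubule regulator of neurons, stood at 273 and 254 CPM with DAPT and at 664 and 526 CPM in untreated cells, and Tubb3 at 5.65 and 3.86 against 14.5 and 16.1 CPM. Against DMSO the neural list was not called. In the pairs with untreated cells, DMSO and coculture, Stmn2 stood at -1.12, -0.697 and -0.348 and Tubb3 at -1.44, -1.41 and -0.00733. Chondrocyte genes were negative in 5 of 6 cases against untreated cells (-1.27, 2.32e-05 and 0.57), and also in 6 of 6 against DMSO (-0.98, 0.000441 and 0.574), where the call ended without DAPT replicate 2. Acan, the core protein of cartilage aggrecan, had 0.00927 and 0.00755 CPM with DAPT and 0.199 and 0.165 CPM untreated. Lists of other cell types were also called, most on few counts. The 4 tested erythroid genes, at most 2.70 CPM in any library, were higher with DAPT than with DMSO (median 3.73, or 2.40 with genes at 0 set to their bound; adjusted p = 0.000193, 0.574 with an estimated correlation; ending without DAPT replicate 2), lower with DMSO than untreated (-2.56, 0.0236 and 0.661), and higher in untreated 12-day cells than in MEFs (7.41, bound 3.60, 0.0381 and 0.566) or 3-day cells (5.90, bound 3.32, 0.00369 and 0.542). With DAPT against DMSO, T-lineage genes (-0.53, 0.0216 and 0.67) and skeletal muscle genes (-0.79, bound 0.0, 0.0164 and 0.583) were called lower, and each call ended without 1 of the DAPT replicates. For T-lineage genes this was replicate 1, the same comparison as with cell origin as a term. Untreated 12-day cells also had lower macrophage genes than MEFs outside the macrophage-like cluster (-5.74, bound -3.26, 0.000798 and 0.566; 6 of 11 fell, at most 1.26 CPM in MEFs) and lower skeletal muscle genes (-3.03, 0.0469 and 0.566; the call ended in 4 of 6 other fits).

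In untreated 12-day cells against MEFs, 6 of 24 genes of Wnt and FGF signalling rose and 3 fell (8 and 3 adjusted over the list alone), with Nkd1 207-fold and Wnt10b 38.2-fold higher and Fgf7 lower, and the list did not move as a set (adjusted p = 0.166). Of 16 genes of p53 and senescence 3 rose (6 adjusted over the list alone; set adjusted p = 0.223), Cdkn1a and Igfbp3 among them. Of 8 skeletal muscle genes 4 fell and 1 rose. Bmp4, which acts on the thymic rudiment, rose 6.44-fold, and Stmn2 89.4-fold. MHC class I (median 1.26, adjusted p = 0.0207), MHC class II (2.26, 0.0469) and interferon genes (0.94, 0.043) were called higher as sets, with adjusted p from 0.566 to 0.707 with an estimated correlation, and without untreated replicate 1 the class II and interferon calls ended (0.0557 and 0.0792).

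Other lists called with the preset correlation alone were chemokines and cytokines (1.03 with DAPT against DMSO, -1.0 for DMSO and -0.72 for coculture against untreated cells), transition regulators (-0.28), cholesterol synthesis (-0.33) and Wnt and FGF genes (-0.21) with DAPT against DMSO, the last also for DMSO against untreated cells (0.48), contractile genes (-0.35) and Notch receptors, ligands and processing (0.24) with DAPT against untreated cells, and contractile genes in coculture (0.52). With DAPT against DMSO, the transition, cholesterol and Wnt calls ended with cell origin as a term and without DAPT replicate 1, which are the same comparison. The Wnt call also ended with joined controls and origin. Against untreated cells, the contractile call with DAPT ended without untreated replicate 1 and without DAPT replicate 1. That of Notch receptors ended in 4 of 7 other fits, among them cell origin as a term and, the same comparison, without DAPT replicate 2. In coculture the contractile call ended in 3 of 6 and the chemokine call without untreated replicate 2. Against 3-day cells they were keratinocyte (2.37), fibroblast (-1.05), transition (-1.14), Notch target (-0.72), unfolded protein response (0.59) and immediate early genes (0.72), of which the unfolded protein call ended in 4 of 6 other fits, the Notch target call in 3 of 6 and the transition call without untreated replicate 2.

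The DAPT libraries of day 12 differed from each other: 13.3% of 10116 genes were over 2-fold apart. Cells of high mitochondrial share or few genes are argued against, since it was 12.5% of 10064 genes under the stricter filter. Thinning every library to the smallest total left it at 13.3%, but decides nothing, as each gene counted still had at least 1031 UMIs in 1 of the 2 libraries, far too many for thinning to move it over the line. Embryo origin may account for it: the difference between the replicates correlated at r = 0.851 with that of DMSO from untreated cells, which shares no library with it but also parts the origins. Batches of culture or processing that follow the origins would give the same value. No label names one, but the matrices of DMSO and DAPT replicate 2 list a GFP sequence, while those of untreated cells and DAPT replicate 1 list none.

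Interferon response genes had positive median log2 ratios with DAPT within each pair of like origin: 0.379 (interval over genes 0.166 to 2.167; 5 of 6 higher) against untreated cells, 0.348 (-0.202 to 1.659; 6 of 10) against DMSO and 0.401 (0.245 to 1.878; 9 of 10) against coculture. Origin alone would give medians under 0.1, but the smallest, 0.348, has an interval that includes 0, so this stays open. A few strongly responding cells could hold much of the signal: the top 1% of cells held 24.8%, 44.1% and 38.3% of the list's UMIs in DAPT replicates 1 and 2 and the 10-day DAPT library, against 15.9% to 21.4% in the untreated, DMSO and coculture libraries, a result between the predicted bounds. Without those cells the list's summed CPM was 80.95 with DAPT against 63.42 and 70.39 untreated, 142.5 against 107.8 with DMSO, and 108.6 against 112.1 in coculture, but these cells were picked by the list's own UMIs and single libraries give no spread, so the values do not decide it. Macrophage-like cells are argued against: at the ratio of the lists inside the cluster, their list would have to rise by 655.4 CPM or more. It changed by -0.02958, 0.31 and -11.53 CPM (highest counting limit 0.7386). The list was higher with DAPT in 1 of the 3 pairs, but this count decides nothing, since of these libraries only the coculture held such cells. An effect of DAPT itself, the biological alternative, was not excluded and is confounded with coculture in the mixed pair.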
